A study of Mus musculus with 6 samples.

How the data were processed

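Polyadenylated RNA from the ventricles of 6 single mouse embryos of embryonic day 12.5, on a C57BL/6 background, was sequenced. Per the labels' protocols, the atria and the region of the valves had been removed from each heart, 500 ng of total RNA went into each TruSeq library, and single reads of 75 bp were made on a Genome Analyzer IIx. The control group held 3 embryos with 2 floxed Vhl alleles and wild-type Nkx2-5. The group labelled Vhl knockout held 3 embryos labelled as having 2 floxed Vhl alleles and 1 Nkx2-5 allele that carries Cre recombinase. Cre is made in heart muscle progenitors and cuts out the floxed part of Vhl. No group labelled as having Cre and intact Vhl was analysed here, so the groups as labelled differed by Vhl and by the Cre allele together. Per the labels, control 1 and knockout 1 came from litter 1, control 2 and knockout 2 from litter 2, control 3 from litter 3 and knockout 3 from litter 4, while the series' design text speaks of 3 litters.

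Per the submitters' processing notes, the tools used were CASAVA 1.8.2, cutadapt 1.3 and RSEM 1.2.3 with the GRCm38 mouse genome. The annotation release, the gene filter and the scaling were not given in the sources used here. The deposited table held a normalized signal for 13843 genes, and the columns summed to between 987131 and 1017770 rather than to 1 common total. In each column 100% of the values were whole multiples of 1 step, within a tolerance of 0.01 reads, so the authors had divided whole reads per gene by 1 factor per library. The recovered totals were 9067805, 11866333 and 9411323 reads in controls 1 to 3, and 12592902, 11349228 and 10911630 in knockouts 1 to 3. The factors equalled effective library sizes of edgeR's trimmed mean of M values, recomputed on the recovered reads, at a ratio of 1 in all 6 libraries. Every gene in the table had a value of at least 1 in at least 3 libraries, so low genes had been removed before deposit. Gene identifiers were matched to GENCODE M21 on GRCm38 for names and coordinates, which gave a symbol for 13675 genes and left 168 without one. RSEM shares out reads that match several loci, so values of close copies and pseudogenes are uncertain, as are those of overlapping genes, because the libraries did not mark strand.

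The design fixed before the data were examined had expected read counts and named limma as the test should the table hold normalized values, which it did. The main test was therefore limma 3.58.1 with trend, in R 4.3.3, on log2(value + 1), with all 6 libraries, no covariate and Benjamini-Hochberg adjusted p under 0.05. Fold changes are on that scale, labelled knockout over control, which understates the change of low genes. Because the comparison rests on single embryos of 3 and 3, p-values measure the spread between embryos, with the variance of each gene moderated by other genes. With litters 1 and 2 alone and litter as a block, 1 residual degree of freedom is left, so that spread is mostly pooled over genes. The 37 gene lists were fixed before the data were examined, from general knowledge of hypoxia signalling and of the embryonic heart, and the 33 with at least 5 measured members were tested. Some lists share members, so their results are not all independent. The list test was camera with a preset correlation of 0.01 between genes, adjusted over the 33 lists, with camera on an estimated correlation and fry beside it. In the fit of litters 1 and 2 alone, the last 2 tests have little power, because 1 residual degree of freedom is left. A list they did not call there is not thereby argued against. Named genes were Vhl, Nkx2-5, Hif1a, Epas1 and Arnt. To these came the 10 largest changes in each direction among genes past the threshold with a mean in the upper part of tested genes (above the median, 27.3) and no overlap between groups, without clone names. From each list came up to 4 members with the smallest p. The middle part of that rule named 0 genes with all 6 libraries and was applied to the fit without the library labelled knockout 3.

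The value of Vhl in the library labelled knockout 3 went against its label. No library was given another label. Each comparison was made with all 6 libraries, then without that library (3 controls against knockouts 1 and 2, a leave-one-out fit planned beforehand), and for the littermates of litters 1 and 2 with litter as a block (2 against 2, planned beforehand and not chosen from any value). Leaving out a library because of its Vhl value makes the Vhl difference in that fit partly circular. Genes that followed Vhl over the libraries, such as Hif1a and Egln1, share this limit in part, as do the counts of that fit. The pairing comes from the litters in the labels. Deviations from the group means correlated at 0.20 over genes within litter 1 and at 0.28 within litter 2, and at 0.01 for the libraries numbered 3, which came from different litters. With litter as a block, the libraries of litters 3 and 4 have no littermate and add nothing to the genotype estimate. Pairs of libraries differed by 6.81 to 27.6 chi-square units per gene in their recovered reads, where sampling noise gives about 1, so no library was a second deposit of another.

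Alternatives were edgeR 4.0.16, DESeq2 1.42.0 and voom on the recovered reads, other scalings, pseudocounts of 0.1 and 5, a stricter filter, Xist as a covariate, erythroid or mitochondrially encoded genes left out, blocks by litter or by title number, and each library left out. The robust edgeR test, the exclusion of genes near Nkx2-5 and all alternatives without the library labelled knockout 3, apart from that leave-one-out fit itself, were added after seeing the data. On simulated reads for the 13843 genes of the 6-library comparison, limma called 50.7% of 67 genes changed 1.5-fold, 92.5% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 9 false calls. For the comparison without the library labelled knockout 3 these shares were 50.7%, 91.0% and 100%, with 7 false calls. The simulated reads took their dispersion from the controls alone and gave every knockout the full change. Only genes with a control mean of at least 5 were changed. The real library labelled knockout 3 had Vhl at the level of the controls, so the shares for 6 libraries do not apply to the real 6-library comparison. A gene with no read in a library can have had up to 3 reads by chance, a value of 0.24 to 0.33 depending on the library, and this floor covers counting error only.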

Results

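RNA of single embryonic ventricles was sequenced to compare hearts in which Vhl is deleted by a Cre allele at Nkx2-5 with hearts of control embryos. Vhl encodes the protein that marks hypoxia-inducible factors (HIF) for degradation when oxygen is present. The title of the series sets the comparison in the metabolism and maturation of the embryonic heart. There were 3 control libraries and 3 libraries labelled knockout, with 9067805 to 12592902 reads each over 13843 genes. Values are CPM scaled by normalization factors, as deposited. Levels are given as the control mean ± SD (n = 3), followed by the values of single knockout libraries.

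The targeted gene checked the labels. Vhl (ENSMUSG00000033933, chromosome 6, 113623959 to 113631633 on GRCm38) stood at 33.7, 36.3 and 38.6 in controls 1 to 3, at 11.1 in knockout 1 and 10.3 in knockout 2, but at 34.5 in the library labelled knockout 3, inside the range of the controls. Hif1a (chromosome 12, 73901375 to 73947530), which encodes the oxygen-regulated HIF-1 alpha subunit, had values of 457, 405 and 447 in the controls, 185 and 163 in knockouts 1 and 2, and 473 in the library labelled knockout 3. Egln1, an oxygen-sensing hydroxylase gene that HIF induces, was at 109 ± 1.78 in controls, at 297 and 319.7 in knockouts 1 and 2, and at 112 in the library labelled knockout 3. Nkx2-5 (chromosome 17, 26838664 to 26845009), the cardiac transcription factor gene that carries Cre in the knockouts, was at 75.7, 79.2 and 68.6 in controls, 51.6 and 66.7 in knockouts 1 and 2, and 80.3 in the library labelled knockout 3. Over all genes, the first principal component held 38.3% of the variance and placed the library labelled knockout 3 at -15.4, between the controls at -16.5 and -8.78, while knockouts 1 and 2 lay at 28.7 and 24.8. The label of knockout 3 is therefore contradicted by its Vhl value, and every value given for all 6 libraries includes it.

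**Figure D1:**
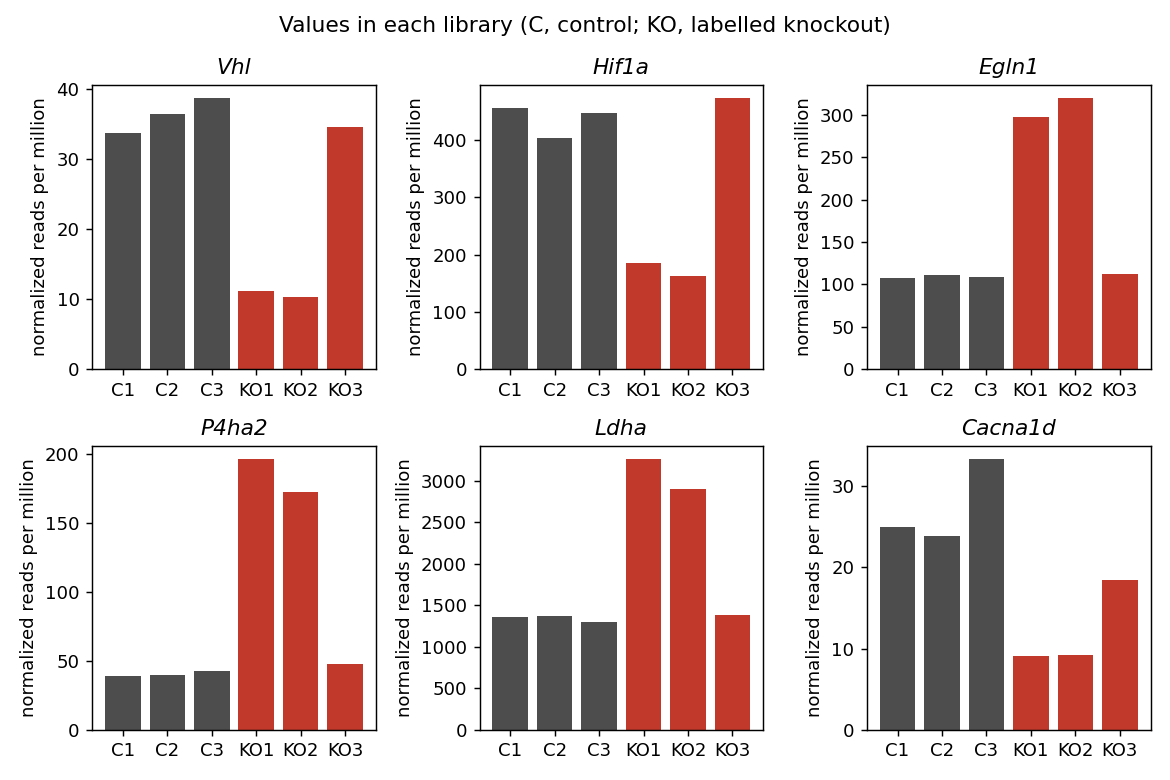
Deposited normalized values of 6 genes in each library, as bars from 0; C1 to C3 are controls and KO1 to KO3 the libraries labelled knockout. Vhl was at 11.1 and 10.3 in knockouts 1 and 2 and at 34.5 in the library labelled knockout 3, and Egln1, P4ha2 and Ldha of that library lay near the controls, while its Cacna1d value of 18.5 lay below all 3 controls.

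With all 6 libraries as labelled, 0 genes passed the threshold in either direction. The smallest adjusted p of limma was 0.77, and 859 of 13843 genes had an unadjusted p under 0.05. The edgeR test on recovered reads also called 0 genes (879 at an unadjusted p under 0.05), and DESeq2 called 7 higher and 4 lower, the last being Cdo1, Tln2, Cmya5 and Cacna1d. The log2 fold change of Vhl was -1.14 ± 0.39 (SE, adjusted p = 0.77), that of Hif1a -0.84 ± 0.35 and that of Nkx2-5 -0.19 ± 0.15. Values of the 3 controls and the 3 libraries labelled knockout did not overlap for 1354 genes, 9.78%, where chance gives 10%. Litter as a block, which takes the genotype difference from litters 1 and 2 alone, gave 669 genes higher and 459 lower, and leaving out the library labelled knockout 3 gave 416 higher and 172 lower. Among the 33 tested lists, camera put 6 higher and 9 lower with all 6 libraries. The higher lists were HIF targets (median log2 fold change 0.81), glycolysis (0.43), epicardial (0.37) and endothelial markers (0.20), immediate early genes (0.17) and collagen modification (0.13). The lower ones were the macrophage (-0.29), conduction (-0.21), TCA cycle (-0.17), fatty acid oxidation (-0.16), trabecular (-0.16), mitochondrially encoded (-0.16), oxidative phosphorylation (-0.09), cardiac transcription factor (-0.09) and mitochondrial biogenesis lists (-0.07). None of these 15 calls held with an estimated correlation between genes, where the smallest adjusted p was 0.44, and fry called 0 lists. Adjusted over the list alone, 17 of 34 HIF targets were higher and 6 of 30 conduction genes lower with all 6 libraries. So was Tbx5 (log2 -0.43 ± 0.09), the 1 gene lower in each of the cardiac transcription factor and atrial lists, and no gene of another list passed that way.

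Knockouts 1 and 2, whose Vhl values matched their labels, differed from the 3 controls in 588 genes, of which 416 rose and 172 fell (limma, 5 libraries). In the littermate comparison of litters 1 and 2, with litter as a block, 681 rose and 444 fell. That fit had 1 residual degree of freedom, so its p-values rest mostly on a spread pooled over genes. Its higher count is therefore no stronger evidence. The littermate comparison shares both knockouts and 2 of the controls with the comparison of 5 libraries. The 585 of the 588 genes it also called, in the same direction, are therefore no independent support. Vhl fell by 1.67 on the log2 scale (SE 0.11, adjusted p = 0.00025; littermates, 7.4e-06), a difference that was also the ground for leaving out the library labelled knockout 3 and is partly circular. Hif1a mRNA fell by 1.32 (SE 0.09, adjusted p = 0.00025), the largest fall among genes under the naming rule, whose expression floor Vhl did not reach. Epas1, which encodes HIF-2 alpha, and Arnt, the shared beta subunit, stood at 61.4 ± 5.45 and 79.8 ± 2.39 in controls and at 65.5 and 60.4, and 78.4 and 75.01, in knockouts 1 and 2 (adjusted p = 0.89 and 0.75). Nkx2-5 had a log2 fold change of -0.34 ± 0.12 and did not pass with 5 libraries (adjusted p = 0.19), while it passed between littermates (0.029). The count depended on single embryos. Without control 2, 219 genes were higher and 60 lower, and without control 3, 259 and 83. Without knockout 1 the counts were 146 and 44, without knockout 2 they were 236 and 55, and without control 1 the number lower was 90. With 1 knockout left, its spread was assumed to be that of the controls.

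The first 2 of the 10 largest rises under the naming rule were pseudogenes, Atp6v0c-ps2 (chromosome 6, 37806086 to 37806550) and Rps2-ps10 (chromosome 18, 61259008 to 61259972). Atp6v0c-ps2 had no read in any control and values of 88.3 and 90.4 in knockouts 1 and 2, at least 298-fold above a floor of 3 reads per control library, and the library labelled knockout 3 had 1.92. Its parent gene Atp6v0c was among the 10 largest falls, from 182 ± 15.5 to 109.7 and 86.6, so the values of this pair, which can share reads, are uncertain. Rps2-ps10 had values of 0, 1.43 and 0 in the controls and 97.6 and 120.0 in knockouts 1 and 2. Then came A2m, a secreted protease inhibitor (2.02 ± 0.888 in controls, 103 and 92.4 in knockouts 1 and 2), and Nrn1, a neurite outgrowth factor (2.28 ± 0.310, 99.01 and 69.8). The histocompatibility genes H2-Ab1 (2.70 ± 0.917, 70.6 and 64.2) and H2-K1 (8.70 ± 1.55, 118 and 85.96), both on chromosome 17, rose by 4.24 and 3.40 on the log2 scale. The remaining rises were Mgarp, a mitochondrial protein gene (log2 3.71 ± 0.32), the glucose transporter Slc2a3 (2.97 ± 0.22), the metallothionein Mt1 (2.87 ± 0.13) and the secreted glycoprotein Stc2 (2.59 ± 0.18). Besides Hif1a and Atp6v0c, falls under the naming rule included those of the mitochondrial folate enzyme Aldh1l2 (log2 -1.19 ± 0.12), the arrestin Arrdc4 (-0.92 ± 0.14) and the interferon-inducible GTPase Gbp4 (-0.90 ± 0.15). Next came the GABA transaminase Abat (-0.87 ± 0.08), the muscle ubiquitin ligase Fbxo32 (-0.82 ± 0.18), the aldehyde dehydrogenase Aldh1b1 (-0.82 ± 0.07) and the translation factor Eef1a2 (-0.81 ± 0.10). In the library labelled knockout 3, Mt1 was at 15.8 beside 12.3 ± 1.83 in controls, and Slc2a3 at 38.4 beside 43.3 ± 8.58.

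HIF targets rose as a group in knockouts 1 and 2. Of 34 measured members 27 were higher, 0 lower and 7 did not pass, with a median log2 fold change of 1.14 (camera adjusted p = 6.4e-40; adjusted p = 0.12 with an estimated correlation; fry 0.0028). Adjusted over the list alone, 31 were higher and 1 lower, the growth factor gene Pgf (4.72 ± 0.985 to 2.10 and 2.72). The collagen prolyl hydroxylase P4ha2 went from 40.3 ± 1.82 to 196 and 173 (log2 2.17 ± 0.08), Egln1 rose by 1.49 ± 0.07, the adenylate kinase Ak4 by 1.43 ± 0.06 and the lactate exporter Slc16a3 by 1.68 ± 0.08. Between littermates 31 of the 34 rose and 1 fell. In that fit the list had a fry adjusted p of 0.17, and camera gave an adjusted p of 0.59 with an estimated correlation. Each of these 2 tests called 0 of the 33 lists between littermates. With 1 residual degree of freedom both have little power, and the sarcomere and glycogen lists had the same 0.59. These 2 tests therefore do not argue against the HIF target list there.

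Enzymes of glycolysis rose with them. Of 31 measured members of the glycolysis and lactate list, 17 were higher and 1 lower, with a median of 0.62 (camera adjusted p = 2.1e-10; adjusted p = 0.37 with an estimated correlation; fry 0.013), and 18 and 6 adjusted over the list alone. The phosphofructokinase genes Pfkl (286 ± 15.2 in controls, 626 and 627 in knockouts 1 and 2) and Pfkp (266 ± 8.34, 601 and 552) rose by 1.13 and 1.11. Pdk1, a kinase that inhibits pyruvate dehydrogenase, went from 239 ± 1.34 to 557 and 494. Lactate dehydrogenase A, Ldha, rose from 1346 ± 38.9 to 3264 and 2899 (log2 1.19 ± 0.10, adjusted p = 0.00076). The member that fell was Pdk2, another kinase of pyruvate dehydrogenase (log2 -0.75 ± 0.09). Between littermates 2 members of this list fell. In the library labelled knockout 3, Pfkl was at 304 and Ldha at 1379. In the glycogen list 5 of 16 members rose and 1 fell, or 5 and 5 adjusted over the list alone, and 2 fell between littermates. The glycogen synthase Gys1 rose (0.93 ± 0.07), as did the phosphatase subunit Ppp1r3b (0.75 ± 0.06), the phosphoglucomutase Pgm1 (0.98 ± 0.08), the branching enzyme Gbe1 (0.99 ± 0.09) and the phosphorylase Pygl (1.00 ± 0.10), while the muscle phosphorylase Pygm fell (-0.54 ± 0.07). The glycogen list as a whole was not called (camera adjusted p = 0.36; its median of -0.07 and its mean of 0.14 differ in sign, and the test's direction was up). Without knockout 2 it was higher (adjusted p = 0.042; adjusted p = 0.69 with an estimated correlation), with a median of 0.07.

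**Figure D2:**
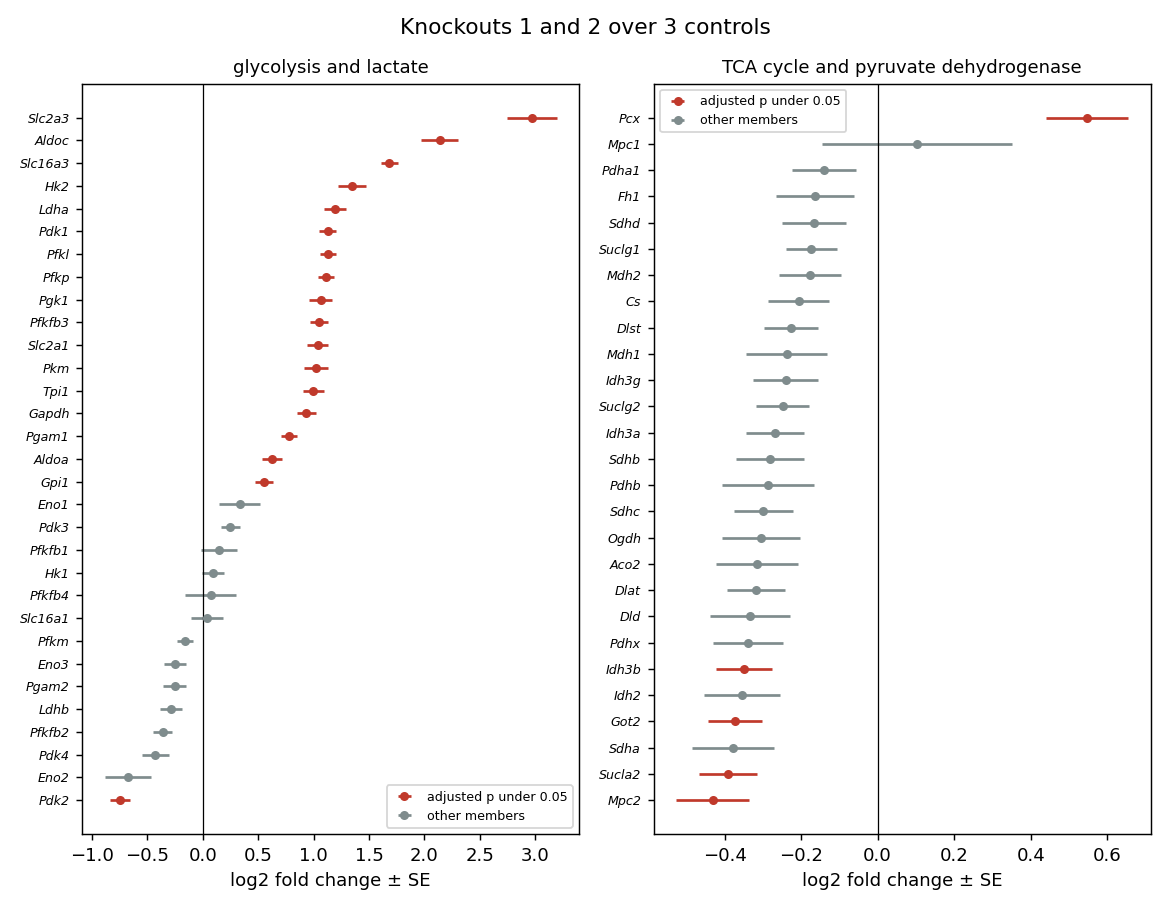
Log2 fold changes of knockouts 1 and 2 over the 3 controls, with SE bars, for each measured member of the glycolysis list (left) and the TCA cycle list (right), red where the adjusted p was under 0.05. On the left 17 members rose and 1 fell, and on the right 4 fell and 1 rose.

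Lists of mitochondrial metabolism were lower, by smaller steps. In the list of the TCA cycle and pyruvate dehydrogenase, 4 of 27 members fell and 1 rose, and 25 of 27 had a fold change below 0. The list median was -0.28 (camera adjusted p = 2.1e-10; adjusted p = 0.44 with an estimated correlation; fry 0.12). Adjusted over the list alone, 19 were lower and 1 higher, and between littermates 14 fell and 1 rose over all genes. Without knockout 2 the median was -0.19, and -0.10 with the library labelled knockout 3 kept. The members that fell were the aspartate aminotransferase Got2 (-0.37 ± 0.07), the succinyl-CoA ligase Sucla2 (-0.39 ± 0.08), the isocitrate dehydrogenase Idh3b (-0.35 ± 0.07) and the pyruvate carrier Mpc2 (-0.43 ± 0.09), and the pyruvate carboxylase Pcx rose (0.55 ± 0.11). In fatty acid uptake and oxidation 4 of 26 fell, 5 adjusted over the list alone, with a median of -0.20 (camera adjusted p = 8.3e-06; adjusted p = 0.52 with an estimated correlation; fry 0.21). The 4 were Eci1 (-0.67 ± 0.08), Etfa (-0.44 ± 0.08), Crat (-0.45 ± 0.10) and Cpt1b, the muscle form of the enzyme that brings fatty acids into mitochondria (-0.51 ± 0.10). Of the 80 nuclear genes of oxidative phosphorylation 2 fell and 2 rose, adjusted over the list alone too, with a median of -0.11 (camera adjusted p = 2.6e-07; adjusted p = 0.63 with an estimated correlation; fry 0.34). Cox6a2 (-0.62 ± 0.07) and Ndufa4 (-0.54 ± 0.08) fell, and Ndufv3 (0.68 ± 0.12) and Cox4i2, a hypoxia-linked form of cytochrome oxidase subunit 4 (1.28 ± 0.974 in controls, 41.6 and 37.5 in knockouts 1 and 2), rose. All 13 mitochondrially encoded genes had fold changes below 0, and 3 fell, namely mt-Nd6 (-0.63 ± 0.10), mt-Nd4l (-0.49 ± 0.09) and mt-Nd5 (-0.68 ± 0.13), or 5 adjusted over the list alone. The list median was -0.29 (camera adjusted p = 2.3e-06; adjusted p = 0.44 with an estimated correlation; fry 0.078). The list of mitochondrial biogenesis was lower (median -0.12, camera adjusted p = 0.012; adjusted p = 0.44 with an estimated correlation; fry 0.15) with 0 of 19 members past the threshold by either adjustment. Ppargc1a, its coactivator gene, was at 107 ± 15.8 and 81.6 and 72.5. Without knockout 2 the calls of oxidative phosphorylation (adjusted p = 0.25, median -0.02), fatty acid oxidation (0.051, median -0.11) and mitochondrial biogenesis (0.051, median -0.14) were lost, the last one also without control 1 (0.070, median -0.11) and with a stricter filter (0.053, median -0.12). Between littermates the members lower over all genes were 9 for oxidative phosphorylation, 9 for fatty acid oxidation and 4 for mitochondrial biogenesis. In the list of mitophagy and autophagy, the mitophagy receptors Bnip3 (1.98 ± 0.13) and Bnip3l (1.05 ± 0.09) rose and the mitophagy kinase Pink1 fell (-0.54 ± 0.09), also adjusted over the list alone, and the other 14 did not pass (list camera adjusted p = 0.67).

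Genes of conduction and ion channels were lower in knockouts 1 and 2 (median -0.31, camera adjusted p = 1.8e-05; adjusted p = 0.2 with an estimated correlation; fry 0.028). Of 30 members 3 fell and 0 rose, 11 adjusted over the list alone, and 10 between littermates over all genes. The 3 were the calcium channel Cacna1d (27.4 ± 5.17 in controls, 9.13 and 9.20 in knockouts 1 and 2, 18.5 in the library labelled knockout 3), the sodium channel subunit Scn4b (2.29 ± 0.256, 0.242 and 0.438) and the potassium channel Kcnd3 (10.2 ± 2.33, 3.80 and 4.56). Tbx5, a cardiac transcription factor, was at 57.4 ± 4.73 in controls, 40.01 and 44.4 in knockouts 1 and 2 (adjusted p = 0.052) and 42.03 in the library labelled knockout 3. The cardiac transcription factor list was lower (median -0.16, camera adjusted p = 0.0018; adjusted p = 0.32 with an estimated correlation; fry 0.1) with 0 of 27 members past the threshold and 3 lower adjusted over the list alone. Its call was lost without knockout 1, where the median was -0.13. The fixed list of contractile genes of the sarcomere showed no shift as a list. In the sarcomere list 1 of 31 members passed, the atrial light chain Myl7 (662 ± 67.4 to 1275 and 1109.8), adjusted over the list alone too (camera adjusted p = 0.79, median -0.03, mean 0.01). In calcium handling Casq1 rose (0.78 ± 0.13) and Camk2a (-0.40 ± 0.07) and phospholamban, Pln (1104 ± 29.2 to 815 and 667), fell, out of 19 members, with 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.36). No member of the trabecular list (16 members; 3 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.15) or of the compact myocardium list (13; 2 and 1; 0.91) passed over all genes. The trabecular list was lower without control 3 (adjusted p = 0.035), without knockout 1 (0.023) and between littermates (0.0076), and the calcium list was lower without knockout 1 (0.035). With an estimated correlation the trabecular adjusted p values were 0.59, 0.67 and 0.59 in that order, and the calcium adjusted p was 0.72. Of the atrial cardiomyocyte list (13 members; 1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.88), Myl7 was the member that passed. Between littermates, 1 trabecular gene was higher and 6 lower over all genes, 4 cardiac transcription factor genes were lower, 3 calcium genes were higher and 4 lower, and 2 atrial and 1 sarcomere genes were lower.

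Of the marker lists of other cell types of the heart, 3 were called, and none of the 3 held with an estimated correlation. Epicardial markers were higher (median 0.53, camera adjusted p = 5.6e-09; adjusted p = 0.38 with an estimated correlation; fry 0.088), with 5 of 15 members past the threshold and 10 adjusted over the list alone. The 5 were the keratin Krt19 (42.7 ± 7.03 to 268 and 210.1), complement C3 (1.39 ± 1.07 to 13.01 and 12.97), the transcription factor Wt1 (32.5 ± 4.21 to 52.9 and 56.96), the retinoic acid enzyme Aldh1a1 (2.99 ± 1.15 to 15.8 and 8.41) and the uroplakin Upk1b (18.2 ± 2.93 to 40.7 and 27.4). Endothelial and endocardial markers were higher (median 0.41, camera adjusted p = 6.7e-10; adjusted p = 0.2 with an estimated correlation; fry 0.028), with 6 of 22 members past the threshold and 14 adjusted over the list alone. Among the 6 were Icam2 (36.8 ± 0.266 to 58.8 and 57.5), the VEGF receptor Flt1 (0.47 ± 0.07), Cd34 (0.53 ± 0.08) and Egfl7 (0.46 ± 0.08). Of 10 smooth muscle and outflow tract markers 4 rose, adjusted over the list alone too, namely Acta2 (933 ± 116 to 1569 and 1515), Cnn1 (0.49 ± 0.09), Notch3 (0.50 ± 0.09) and Tagln (1.24 ± 0.26). The list was higher (camera adjusted p = 0.0094; adjusted p = 0.44 with an estimated correlation; fry 0.27) except without knockout 2 (0.051, median 0.13). The list of collagen modification and matrix was higher (median 0.28, camera adjusted p = 7e-07; adjusted p = 0.17 with an estimated correlation; fry 0.0037). Its 5 of 23 members past the threshold (7 adjusted over the list alone) were the hydroxylases P4ha2, P4ha1 (0.98 ± 0.11), Plod1 (0.63 ± 0.07) and Plod2 (1.42 ± 0.11) and the lysyl oxidase Loxl2 (313 ± 18.4 to 820.5 and 709.5). P4ha2 was also a member of the HIF target list, so the results of these lists are not independent. Of 16 angiogenic factors 6 rose over all genes, and 6 rose and 2 fell adjusted over the list alone, among them Vegfa (139 ± 16.03 to 280.4 and 295), Apln (4.04 ± 1.55 to 16.8 and 17.6), Edn1 (1.10 ± 0.16) and Adm (2.29 ± 0.34). The list was not called (camera adjusted p = 0.12). No member of the mesenchymal and valve (19 members), erythroid (22), macrophage (13) or neuronal (5) lists passed over all genes. Adjusted over the list alone 1 neuronal gene, Elavl3 (log2 -0.86 ± 0.24), was lower. The lists had camera adjusted p of 0.99, 0.67, 0.087 and 0.087. These lists followed single embryos. The erythroid list was higher without knockout 1 (adjusted p = 3.4e-06) and lower without knockout 2 (0.0014), and lower between littermates (0.041), with adjusted p = 0.57, 0.69 and 0.84 with an estimated correlation. Without control 1 the macrophage (5.2e-05), mesenchymal (0.019) and neuronal lists (0.022) were lower, the last one also without knockout 2 (0.042). With an estimated correlation these had adjusted p = 0.44, 0.39, 0.40 and 0.69. Lists of neighbouring tissues had too few measured members for a list test. Liver and gut had 2, of which Apob was lower (6.99 ± 2.67 to 2.18 and 0.613). Skeletal muscle had 3, of which Ckm was lower (23.9 ± 8.71 to 9.78 and 7.71). Lung epithelium had 1, which did not pass. The falls of Apob and Ckm cannot be assigned to neighbouring tissue rather than to the heart itself from these values. Between littermates, 11 epicardial and 1 mesenchymal genes were higher over all genes, 1 erythroid gene was higher and 1 lower, and 3 angiogenic genes were lower.

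**Figure D3:**
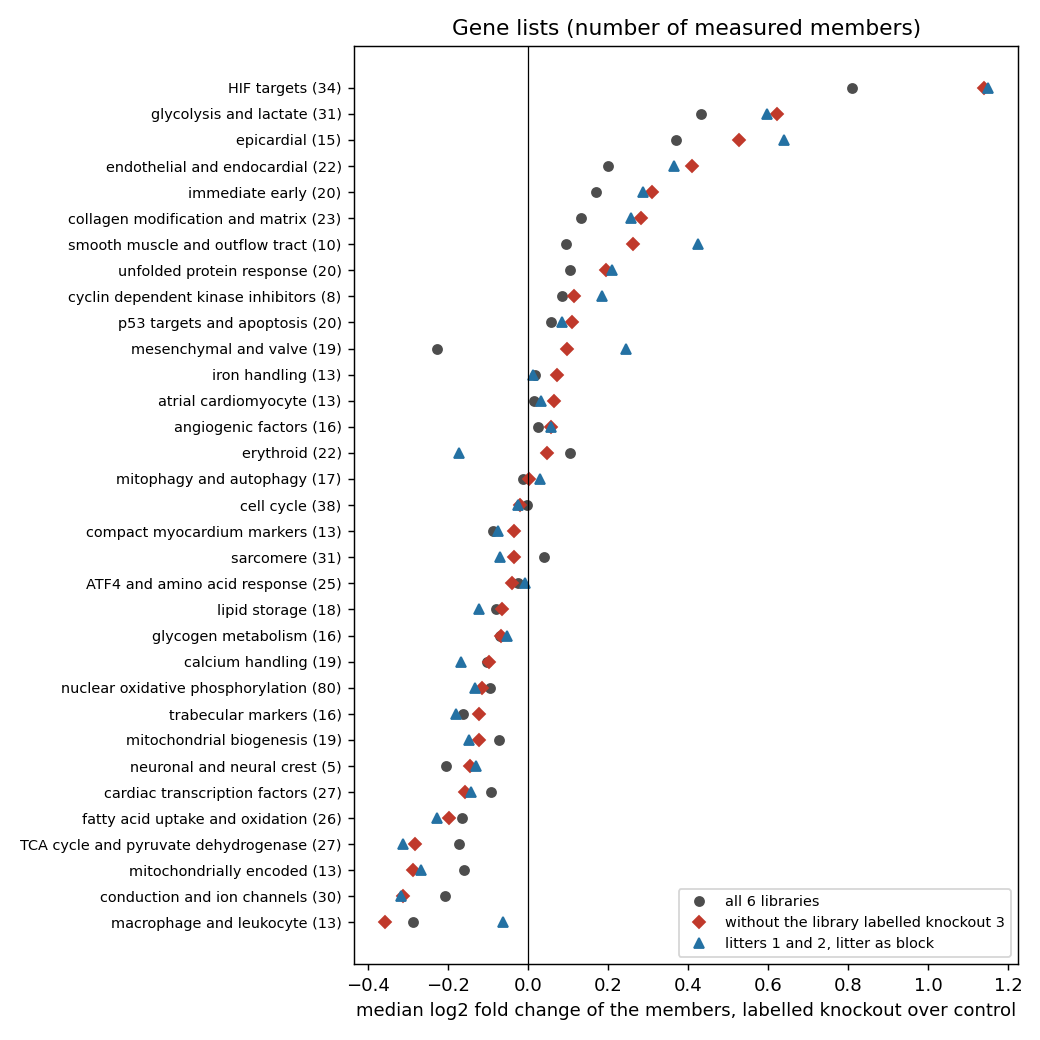
Median log2 fold change, labelled knockout over control, of the members of each tested list, with the number of measured members in parentheses, for all 6 libraries, without the library labelled knockout 3, and for litters 1 and 2 with litter as a block. The HIF target list lay highest in each comparison, at 0.81, 1.14 and 1.15, and the mesenchymal, erythroid, sarcomere and mitophagy medians differed in sign between comparisons.

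No gene of the cell cycle list passed (38 members, 0 adjusted over the list alone, camera adjusted p = 0.68). Of 8 cyclin-dependent kinase inhibitors Cdkn1a (19.2 ± 1.39 to 30.8 and 32.9) and Cdkn2d (36.6 ± 1.86 to 47.4 and 50.9) rose, adjusted over the list alone too (camera adjusted p = 0.13). Of 20 p53 targets and apoptosis genes Cdkn1a and the DNA polymerase Polk (0.55 ± 0.11) rose, by both adjustments (camera adjusted p = 0.16). In the ATF4 and amino acid list the mitochondrial folate genes Mthfd1l (38.4 ± 2.51 to 114 and 102) and Shmt2 (63.1 ± 4.65 to 123 and 139) and the lipoprotein receptor Vldlr (1.13 ± 0.16) rose and Aldh1l2 fell, out of 25 members, with 4 and 1 adjusted over the list alone (camera adjusted p = 0.14; median -0.04, mean 0.14, test direction up). The unfolded protein response list was higher (median 0.20, camera adjusted p = 0.0011; adjusted p = 0.44 with an estimated correlation; fry 0.088) with 0 of 20 members past the threshold and 3 adjusted over the list alone. The immediate early list was higher (median 0.31, camera adjusted p = 0.0018; adjusted p = 0.37 with an estimated correlation; fry 0.028), where Ier3, on chromosome 17, was the 1 of 20 members past the threshold (7.61 ± 0.382 to 38.8 and 35.8) and 4 were higher adjusted over the list alone. In lipid storage Hilpda (8.09 ± 0.596 to 22.1 and 15.9) and the lipid droplet coat Plin2 (41.2 ± 0.240 to 60.2 and 53.3) rose out of 18, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.42). No gene of the iron list passed (13 members, 0 adjusted over the list alone, camera adjusted p = 0.75). Between littermates, 5 immediate early, 2 unfolded protein response and 1 iron genes were higher over all genes, and 2 lipid storage, 2 ATF4 and 1 p53 list genes were lower. The sex-linked list had 1 measured member, Xist, which did not pass.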

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

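Most alternatives for all 6 libraries were fixed before the data were examined. The robust edgeR test, the exclusion of genes near Nkx2-5 and the alternatives of the 5-library comparison were chosen after seeing the data. The alternative with no filter was not run because the table had already been filtered. With all 6 libraries, 0 genes higher and 0 lower (limma, 859 at an unadjusted p under 0.05) became 7 and 4 with DESeq2, 669 and 459 with the replicate block by litter, and 681 and 444 in litters 1 and 2 alone with that block. Leaving out 1 library gave 0 to 416 higher and 0 to 172 lower, the highest values being those without the library labelled knockout 3. The 6 lists higher and 9 lower became 0 and 0 with an estimated correlation and 0 and 0 with fry. The block by title number, which pairs the unrelated libraries numbered 3, gave 0 and 0 genes. Vhl at -1.14 went to -1.63 with either litter fit (adjusted p = 4.0e-06 and 7.4e-06) and ranged from -1.67 to -0.84 with 1 library left out. Nkx2-5 at -0.19 went to -0.39 with either litter fit (adjusted p = 0.028 and 0.029) and ranged from -0.34 (without the library labelled knockout 3) to -0.023 (without knockout 1) with 1 library left out. For Epas1, at 0.02 ± 0.09 over 6 libraries and 0.04 ± 0.10 over 5, leaving out 1 library gave -0.050 to 0.065 and -0.037 to 0.095, with the sign turned without control 2 and without knockout 1 (-0.01 and -0.02). None of these passed the threshold. The cause of these differences was not tested beyond the libraries left out.

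Without the library labelled knockout 3, 416 genes higher and 172 lower became 249 and 75 with Xist as a covariate, 673 and 449 with the replicate block by litter, 178 and 32 at an adjusted p under 0.01, and 147 and 34 with a 2-fold minimum. The number lower was 276 with DESeq2. Leaving out 1 more library gave 146 to 297 higher and 44 to 90 lower. The 8 lists higher and 7 lower became 0 and 0 with an estimated correlation and 5 and 1 with fry. Of the 588 genes, 571 were also called with other size factors, 549 with library size only, 579 with DESeq2, 581 with edgeR, 553 with voom, 585 with the litter block, and 175 to 359 with 1 more library left out. None of the 588 turned direction in any of these fits. Medians of HIF targets, glycolysis and the TCA cycle kept their direction and their camera call at the preset correlation in the alternatives of both comparisons for which lists were tested. The TCA cycle median of -0.17 with 6 libraries and -0.28 with 5 went to -0.10 and -0.19 without knockout 2, and the 6-library value to -0.31 with the litter block. Scalings moved the median of all genes to at most 0.021 from 0 in size. Xist, at 0.61, turned sign with DESeq2 (-0.38), edgeR (-0.38, robust or not), without control 2 (-2.42) and without knockout 2 (-1.80). It reached 3.02 without knockout 1 and passed the threshold in none of these. Of the 15 list calls made with all 6 libraries, those of HIF targets, glycolysis, the TCA cycle, fatty acid oxidation, conduction, endothelial and epicardial genes were kept by camera at the preset correlation in the fits with a list test. The others were lost in at least 1 of them. Leaving out 1 library ended the calls of macrophage (adjusted p up to 0.99, without control 3), trabecular (0.40, without control 1), mitochondrial biogenesis (0.30, without control 1), mitochondrially encoded (0.26, without knockout 2), cardiac transcription factor (0.25, without knockout 1), immediate early (0.25, without knockout 1), collagen modification (0.21 and 0.14, without knockouts 2 and 1) and oxidative phosphorylation genes (0.051, without knockout 2). The stricter filter ended those of macrophage (0.75, median from -0.29 to -0.08) and biogenesis genes (0.069, median -0.07 in both fits). Leaving out genes near Nkx2-5 ended those of trabecular (0.11, median from -0.16 to -0.14) and immediate early genes (0.12, median from 0.17 to 0.11). The litter block ended that of macrophage genes (0.81). In simulated reads with the spread of the controls and the full change in every knockout, changes of 1.5-fold were called in 50.7% of cases. That share does not apply to the 6 libraries as labelled.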

Other observations

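The 488 genes that differed without the library labelled knockout 3 and lay in no fixed list were looked through after their values were seen, and the genes named here were chosen then. The 3 tests of the library labelled knockout 3, both tests of pseudogenes and the test of the cardiomyocyte share were also chosen after seeing the data. Basigin, Bsg, which brings lactate transporters to the cell surface, rose from 465 ± 24.3 to 1409.8 and 1154 (log2 1.46 ± 0.10), and the galactokinase Galk1 from 48.3 ± 4.09 to 132 and 124. The cytokine Mif went from 294 ± 17.5 to 682 and 613, the nuclear receptor Rora from 9.42 ± 0.393 to 53.1 and 45.7 and the copper transporter Atp7b from 6.70 ± 1.72 to 45.2 and 39.4, beside 9.98 in the library labelled knockout 3. The mitochondrial gene Ndufa4l2 rose from 1.65 ± 0.968 to 34.3 and 46.1, while its paralog Ndufa4 fell from 253 ± 6.91 to 185 and 163. The metallothionein Mt2 rose next to Mt1, from 3.79 ± 0.930 to 16.1 and 24.4. The sarcomeric actin Acta1, which the fixed sarcomere list did not hold, rose from 159 ± 29.0 to 390 and 378 (log2 1.28 ± 0.13). Myl7 was therefore not the only contractile gene called. Among genes that fell were Cdo1, an enzyme of cysteine breakdown (23.97 ± 1.84 to 10.6 and 11.5), the phosphodiesterase Pde3a (23.6 ± 0.633 to 12.8 and 12.53) and Aldh5a1, which acts after Abat in the breakdown of GABA (84.1 ± 4.57 to 51.2 and 44.9).

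The library labelled knockout 3 stood with the controls. On a scale from 0, the controls of litters 1 and 2, to 1, their knockout littermates, its median position over the 1125 genes that differed between those littermates was 0.043, against 0.089 for control 3 (difference -0.047), as a wrong label or genotype call of the whole embryo would give. An exchange with a control of this series was argued against by Vhl, because the lowest control lay above both knockouts 1 and 2 by 4.65 times the range of the controls, so that no control was out of place. Whether the embryo carried Cre with Vhl left intact cannot be told apart, since no Cre transcript was measured. The 2 pseudogene copies stood at most at 2.15% of their level in knockouts 1 and 2. Their parent genes Atp6v0c and Rps2 start at 24163866 and 24718116 on chromosome 17, where Nkx2-5 starts at 26838664. Whether reads of these copies come with the Cre allele was not shown, so their low level cannot decide the question. Which embryo the library came from stays open, and no biological explanation was tested.

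Several strong changes lay near Nkx2-5 on chromosome 17, such as those of H2-K1, H2-Ab1 and Rgs11 (log2 3.14 ± 0.22), where a strain haplotype linked to the Cre allele could act in place of Vhl loss. Within 10 Mb, 19 of 326 genes (5.83%) were called against 566 of 13348 elsewhere (4.24%), an odds ratio of 1.40 (95% interval 0.82 to 2.24), so the haplotype cannot be told apart from the genotype for these genes. The 19 also included list members named above. These were Eci1 (fatty acid oxidation), Ndufv3 (oxidative phosphorylation), Notch3 (smooth muscle), Cdkn1a (kinase inhibitors and p53 targets) and Ier3 (immediate early). The same limit holds for their changes. Within 10 Mb of Vhl the odds ratio was 0.71 (0.14 to 2.16), with 3 of 97 genes called, an interval too wide to decide on variants around the floxed locus, which both groups carry. The 3 included A2m and Slc2a3, which start at 121635376 and 122727809 on chromosome 6, against 113623959 for Vhl. Both were among the 10 largest rises under the naming rule. For Atp6v0c-ps2, the sum of parent and copy changed by 0.046 on the log2 scale, from 182 ± 15.5 to 187, while the parent changed by -83.6 and the copy by 89.3, consistent with reads of the parent gene assigned to the copy. For Rps2-ps10 the sum changed by 0.13, between no change and the 0.25 of a pure addition, so shared reads stay open.

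Epicardial markers were higher in knockouts 1 and 2 (adjusted p = 0.38 with an estimated correlation; fry 0.088). The median log2 fold change of Wt1, Tbx18 and Tcf21 was 0.53, with Wt1 at 0.74 ± 0.12 past the threshold and Tcf21 (0.53 ± 0.19) and Tbx18 (0.30 ± 0.10) not. These 3 genes belong to the list itself, so they cannot tell a larger share of epicardial cells from higher expression per cell. A smaller share of cardiomyocytes would raise other cell types alike, whereas medians of 6 such lists ran from -0.36 (macrophage) to 0.53 (epicardial), a range of 0.88. Between littermates the range was 0.81, with the erythroid median lowest at -0.17 and the macrophage median at -0.06. The sarcomere list, which a smaller cardiomyocyte share would lower, had a median of -0.03 (camera adjusted p = 0.79). The gap between the epicardial and macrophage lists widened by 2.59 control SD in knockout 1 and by 1.48 in knockout 2. This is too little beyond the spread to decide, so a smaller cardiomyocyte share cannot be told apart. An effect of Vhl loss on epicardial growth also stays open, untested.

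With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 0 genes, so that all 10 gave at least as many by construction and nothing follows from that count. The highest other split gave 38. It sets control 1, knockout 1 and the library labelled knockout 3 against control 2, knockout 2 and control 3, and points to a structure of the samples. Both embryos of litter 1 stand apart from both of litter 2 there, and the other split that keeps these litters apart gave 3 genes. The second principal component also set control 1 and knockout 1 (23.6 and 17.3) apart from control 2 and knockout 2 (-12.4 and -15.3). With the replicate block by litter, 669 genes were higher and 459 lower.

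In the DESeq2 test of all 6 libraries, the 4 genes called lower had values in the library labelled knockout 3 under every control: Cdo1 at 13.6 (controls 22.9, 26.1 and 22.97), Tln2 at 116 (168, 149 and 177), Cmya5 at 32.1 (54.03, 47.5 and 65.03) and Cacna1d at 18.5 (24.96, 23.9 and 33.4). The 7 genes called higher had values there above every control, such as Pgk1 at 1297 (1147, 1194 and 1146), Slc30a10 at 9.25 (3.66, 6.29 and 2.94) and Atp6v0c-ps2 at 1.92 (0 in each). That test included the library labelled knockout 3 and so favours genes in which it lies on the side of knockouts 1 and 2. Over all genes, 9.78% did not overlap between the labelled groups, where chance gives 10%. Nothing about the genotype of that library follows from these genes. Xist stood at 1499.7, 1.59 and 1348 in controls 1 to 3 and at 48.9, 1407 and 1546 in the libraries labelled knockout. Control 2 and knockout 1 lay far below the other libraries, as embryos of both sexes would give. Why knockout 1 lay above control 2 was not tested. With Xist as a covariate, 321 of the 588 genes called without the library labelled knockout 3 were called again. Leaving out knockout 1 from all 6 libraries called 1 gene, the pseudogene Gm10039 (11.8, 13.01 and 14.5 in controls, 14.6, 49.9 and 57.6 in the libraries labelled knockout), and leaving out knockout 2 called 1, the pseudogene Gm8730 (188, 181 and 181, then 373, 198 and 355).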
